A study of Rattus norvegicus with 20 samples.

How the data were processed

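NF-kB p65 binding was measured on 20 promoter tiling arrays of rat liver, 1 array per sample, in 6 groups by diet and time. Per the labels' protocols, liver was fixed, chromatin was sheared by sonication and precipitated with a rabbit polyclonal antibody against p65, and DNA was labelled by random priming and hybridised to NimbleGen arrays. Per the channel labels, Cy5 held the immunoprecipitated DNA and Cy3 the input DNA, while the labelling text speaks of IgG-precipitated DNA in Cy3, so the nature of the reference was not settled. Groups and replicate numbers were taken from the sample titles, and array run, slide and animal number from identifiers that came with the arrays. These gave 4 runs, 11 slides and 16 animals, 4 of them with 2 arrays. The labels number biological replicates and do not name animals, so p-values measure only the spread between these samples, which may be technical.

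The deposited value table of the authors held 1 log2 ratio per probe and array, for 713735 probes named by chromosome and position. How the authors centred these values was not given in the sources used here, and their medians lay between −0.0249 and 0.0170, with a spread that differed between arrays. The authors' peak lists, 1 per array, gave for each peak its position, the nearest transcription start, a peak score and a false discovery rate (FDR), a p-value type measure, per the file headers. The highest FDR listed was 0.19961, so weaker peaks were not analysed here. The peak caller, its settings and the genome build were not given in the sources used here, and coordinates are printed as the files give them. The direction of the log2 ratio was not stated either: from 99.9% to 100% of the peaks of each array lay below 0 in the deposited table, and across peaks the deposited value and the peak score correlated at r from −0.821 to −0.616. All values were therefore multiplied by −1, which gives the peaks positive signal, and the deposited direction was kept as an alternative. That alternative chose the window of each region anew, by the highest mean in the deposited direction. It thus differs in window as well as in sign.

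Each array was centred on its median, with no loess or quantile step. Probes were joined into tiled regions, which ended at gaps of over 1000 bp. In each region the 500 bp window with at least 4 probes and the highest mean over all 20 arrays was chosen, and the mean of its probes was the promoter signal. Of 14723 regions, with a median of 5325 bp and 50 probes at a median spacing of 100 bp, 14540 had such a window. Gene names came from the transcript accessions of the peak lists, of which 13670 of 14678 matched the reference table (assembly GRCr8, used for names alone) and 3476 were renamed. This named 13129 regions, 1139 of them with several genes, and left 1411 unnamed. Of the listed starts 99.7% lay in a tiled region. No pair of arrays shared over 0.248% of its probe values.

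Promoter signal was tested with limma (version 3.58.1 in R 4.3.3; lmFit, contrasts.fit and eBayes with trend) on all 20 arrays in 1 fit of 6 group means, with Benjamini-Hochberg adjustment over 14540 promoters and a threshold of 0.05. All limma tests were two-sided. The comparisons were ethanol against carbohydrate at each time and over all times, 1h and 6h against 0h in each diet, and the difference between the diets in those changes. Gene lists were tested with camera, with a preset correlation of 0.01 and with the estimated one, and with fry. There were 19 lists: NF-kB targets, immediate early, cytokine and JAK-STAT, acute phase, cell cycle, apoptosis, alcohol and xenobiotic metabolism, lipid metabolism, glucose and amino acid metabolism, liver transcription factors, growth factor signalling, ribosome and translation and testis and neuronal genes (both as comparison lists), and markers of hepatocytes, Kupffer cells and macrophages, stellate cells, sinusoidal endothelium, cholangiocytes, and lymphocytes and neutrophils. Numbers of peaks were compared by exact permutation tests, shared bound genes by permuting the group labels, and the level at NF-kB targets by an exact sign test and 10000 random lists. A gene counted as bound in a group where at least 2 of its arrays had a peak. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these steps. The fit was tested on simulated data with 200 of 14540 promoters changed. The noise was drawn independently for each promoter and array, with no slide or run effect. For ethanol against carbohydrate at 1h the fit recovered 25% of those changed by 0.4 log2 and 96% of those changed by 0.8. At 6h it recovered 32% and 97%, and for 6h against 0h in carbohydrate 24% and 95%. There were 5, 5 and 9 false calls.

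The groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each comparison, the 10 largest rises and the 10 largest falls among promoters with an adjusted p under 0.05 and no overlap between the arrays compared, or, where fewer than 3 passed, the 3 smallest unadjusted p values in each direction as not past the threshold. It also took the 20 genes with peaks on the most arrays (ties by signal), up to 10 genes per direction with a peak on every array of 1 diet and on none of the other, up to 4 members per list that passed over all promoters or over the list alone, and always Nfkbia, Tnfaip3, Cxcl1, Icam1, Nfkb2 and Ccl2. Alternatives were the mean of the tiled region, scaling of arrays to the same median absolute deviation, quantile normalization, array weights, array run as a fixed term, slide or animal number as a random block, the replicate number as a block, the compared arrays alone, each array left out in turn, and stricter or looser peak rules. The tests inside the third array run, the receptor promoters, the deposited direction of the ratio, the ranks of lists other than NF-kB targets in other settings, the level of the lists by time and the fits of single runs were chosen after seeing the data. Some genes that the rule names are not reported here. A search for kappaB motifs was left out because it needs a genome sequence of the files' build, which was not used here.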

Results

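Binding of NF-kB p65, a transcription factor subunit that switches on inflammatory and survival genes, was mapped by chromatin immunoprecipitation on promoter tiling arrays (ChIP-chip) in livers of male Sprague Dawley rats. The rats drank for 5 weeks a liquid diet with 36% of its calories from ethanol, or a pair-fed diet in which carbohydrate took the place of the ethanol. The lobes taken out at a 70% partial hepatectomy, an operation after which the remaining liver grows back, gave the 0h arrays, and the remnant lobes gave the 1h and 6h arrays. Each diet had 3 arrays at 0h, 3 at 1h and 4 at 6h, 20 in all, numbered in the labels as biological replicates. The title of the series names the question: whether long ethanol feeding shifts the promoters that NF-kB binds as the liver regenerates.

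Each array held 713735 probes, and promoter signal is given as the log2 ratio of p65 to reference DNA. The reference was input per the channel labels and IgG-precipitated DNA per the labelling text. Signal was taken over the 500 bp window with the highest mean in each of 14540 tiled promoters, 13129 of them with a gene name. The sign of the ratio was likely as used here but was not stated: on all 20 arrays the authors' own peaks lay at negative deposited values, so every value was turned. The number of arrays limited the precision, with a median standard error of 0.142 for a difference of 3 arrays against 3 and of 0.123 for 4 against 4. Array identifiers placed the arrays in 4 runs, and 5 of the 6 arrays of 0h made up a run with no other time. The sixth, ethanol 0h replicate 2, shared a slide with a 1h array of each diet, and 11 of the 14 later arrays lay in the third run. Pairs of arrays of 1 group correlated at a mean r of 0.448 (SD 0.153, 24 pairs) across probes, and pairs of different groups and runs at 0.220 (SD 0.149, 113 pairs). Pairs of different groups in the same run reached 0.421 (SD 0.159, 53 pairs), and those on the same slide 0.548 (SD 0.168, 11 pairs).

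The authors' peak lists held from 2874 to 9387 peaks per array. Shc3, a signalling adaptor of neurons, Ado, an enzyme of thiol oxidation, and Galnt9, which starts O-linked glycosylation, carried a peak on all 20 arrays. Their mean promoter signals were 0.72 ± 0.26, 0.69 ± 0.11 and 0.43 ± 0.18 (SD, n = 20). Peaks on 19 arrays were listed for 11 genes, among them Dlgap2 and Erich1, which share a promoter, the heart and neural crest transcription factor Hand2, the phosphatase Ptprt, the cytoskeletal protein Epb41l3, Adamts14, Clstn2, Tm4sf20, Tdrd5, Fcgr2al1 and the class I histocompatibility gene RT1-CE14. Pex5l, Rnase4, a secreted ribonuclease, Tenm2, Gpn1 and E230034O05Rik were among those highest in signal of the genes with peaks on 18. In all, 263 genes carried a peak on at least 15 arrays, against 0.908 expected had each array's peaks fallen on genes independently. None of the 20 most often bound genes belonged to the list of known NF-kB targets. With 43 target promoters beside 14356 genes in the peak lists, 20 genes drawn at random would seldom include a target, so this decides nothing.

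Taken over all times, promoters of known NF-kB targets did not carry more signal than other promoters, but the times differed. Their mean lay −0.007 log2 from that of all other promoters over the 20 arrays, above it on 9 arrays and below it on 11 (exact sign test, two-sided, p = 0.824). It lay above on all 6 arrays of 1h (mean 0.05 log2, from 0.01 to 0.08; exact sign test, two-sided, p = 0.0312, the smallest possible) and below on all 8 of 6h (mean −0.06, from −0.08 to −0.02; p = 0.00781), also with the mean of the tiled region, while in the deposited direction it lay below at 1h and above at 6h. This split by time was made after the data were seen, and by the median the list ranked at percentile 50.8 of random lists at 1h and 5.34 at 6h, at 95.2 and 10.6 with the mean of the tiled region and at 31.6 and 87.6 in the deposited direction. The median level of the list over all arrays ranked at percentile 17.9 among 10000 random lists of the same size, at 70.8 in the deposited direction of the ratio and at 46.9 with the mean of the tiled region. Immediate early genes, which answer growth signals within minutes, ranked at 99.7, acute phase genes at 99.9, ribosome and translation genes at 99.4 and glucose and amino acid metabolism genes at 99.5. In the deposited direction these ranks were 76.0, 6.80, 43.2 and 0.430, and with the mean of the tiled region 67.8, 99.9, 99.95 and 99.6. The mean of these lists lay above that of other promoters on 9, 8, 12 and 8 of the 20 arrays (exact sign test, two-sided, p = 0.824, 0.503, 0.503 and 0.503), again as a mixture of times. At 1h they lay above on all 6 arrays (means 0.33, 0.25, 0.19 and 0.27 log2), and at 6h on 0, 1, 4 and 0 of 8, so the excess at 1h also held for the ribosome list, a comparison list. In the deposited direction, which also took other windows, the immediate early, acute phase, ribosome and glucose lists did not show this excess. There all 4 lay above on 0 of 6 arrays of 1h (−0.05, −0.11, −0.06 and −0.17), and the immediate early list on 7 of 8 of 6h. A change of sign alone mirrors these values, so with the turned sign the 4 lists lay above at 1h in these windows too. The excess thus held in both sets of windows, and its direction rests on the sign. By the authors' peaks, 28.9% of 45 NF-kB target genes were bound (a peak on at least 2 arrays) at 1h in carbohydrate-fed rats, as against 28.9% of all genes, and 44.4% against 41.6% in ethanol-fed rats. Of 35 immediate early genes, 62.9% were bound at 1h in carbohydrate-fed and 80.0% in ethanol-fed rats, and 17.1% and 2.86% at 6h. Of 25 acute phase genes, 68.0% and 88.0% were bound at 1h and 28.0% and 8.00% at 6h.

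The arrays at 1h against 0h asked which promoters p65 gains or loses early after the operation. In carbohydrate-fed rats p65 signal rose at Egr1, an immediate early zinc finger factor, from −0.08 ± 0.38 to 1.53 ± 0.19 (SD, n = 3 and 3; log2 difference 1.61 ± 0.28 SE, limma adjusted p = 0.00216). The window lay on chromosome 18 from 27344654 to 27344994. Errfi1, an inhibitor of the epidermal growth factor receptor, rose by 1.74 ± 0.32 (adjusted p = 0.00385) and Crp, the acute phase C-reactive protein, by 1.42 ± 0.23 (adjusted p = 0.0019). The other large rises were at Rin1, a Ras effector (1.33), the metallothionein promoter of Mt1 and Mt2A (1.21), the kinase Camkk1 (1.17), Pbld1 (1.12), the promoter of the splicing regulator Esrp2 and Pla2g15 (1.08, but −0.28 with array run as a term), Anxa8 (1.07) and Actg1, a cytoplasmic actin (1.07). Signal fell at Rybp, a Polycomb protein, by −1.16 ± 0.19 (adjusted p = 0.0019) and at Ahr, the receptor that senses dioxins and other xenobiotics, by −0.76 ± 0.15 (adjusted p = 0.00503). It also fell at the olfactory receptor Or51ac3 (−0.94), Wdfy2 (−0.86), the fucosyltransferase Fut8 (−0.81), the membrane fusion protein Stx18 (−0.75), Mkks (−0.71) and Or1e26b (−0.69).

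Of 35 immediate early promoters in carbohydrate-fed rats at 1h, 11 rose and none fell, among them Igfbp1, which binds insulin-like growth factors (0.97 ± 0.24), Zfp36l1 (0.92), Gadd45g (0.87) and Junb (0.71), and 16 rose adjusted over the list alone. All carbohydrate 0h arrays lay in the first run and no 1h array did, and with array run as a term these 4 turned to −0.19, −0.50, −0.36 and −0.09. Of 26 acute phase promoters 7 rose and 1 fell, 10 and 2 adjusted over the list alone, with rises at albumin, Alb (0.88 ± 0.19), Serpina3n (0.77) and Orm1 (0.59) and a fall at ceruloplasmin, Cp (−0.49). Of 43 NF-kB target promoters 8 rose and 2 fell, 11 and 2 adjusted over the list alone. The risers included Bcl2l1, which blocks apoptosis (0.79 ± 0.17, adjusted p = 0.00717), the shared promoter of the cytokines Lta and Tnf (0.64 ± 0.14, adjusted p = 0.00666), Irf1 (0.60) and Gadd45b (0.56), while Bcl2a1 (−0.38) and Xiap (−0.34) fell. Here too Bcl2l1, Irf1 and Gadd45b turned with array run as a term (−0.13, −0.30 and −0.12). Of 30 glucose and amino acid metabolism promoters 9 rose and none fell, 18 adjusted over the list alone, with Sds (0.77), Hpd (0.76), Mat1a (0.70) and Tdo2 (0.70) as examples. In the lipid list 10 of 40 rose and none fell. In the ribosome and translation list 7 of 40 rose (the promoter of Dapk3, Eef2 and Pias4 by 1.03 and that of Commd5 and Rpl8 by 1.00). In the cytokine and JAK-STAT list 7 of 36 rose (Tnfrsf1a, a receptor for tumour necrosis factor, by 0.85) and 1 fell (Ripk1, −0.48). Among the other lists 5 alcohol and xenobiotic metabolism promoters rose and 2 fell (Gstm1 0.94, Ugt2b1 −0.49), and 5 of liver transcription factors rose (Atf4 0.83, Hhex 0.80). Further, 6 of growth factor signalling rose, and 4 of apoptosis rose and 2 fell (Bax 0.73, Casp1 −0.54). In the cell cycle list 3 rose and 2 fell (Cdkn1c 0.62, Cdkn2a −0.53), and 3 of the testis and neuronal comparison list rose and 1 fell. Of markers of liver cell types, 3 of hepatocytes, 2 of Kupffer cells (C1qb 0.73), 2 of stellate cells (Gfap 0.46) and 1 of sinusoidal endothelium (Tie1 0.56) rose, 1 of cholangiocytes fell (Cftr −0.35), and none of lymphocytes and neutrophils passed. The direction also turned with array run as a term at Hpd, the promoter of Dapk3, Eef2 and Pias4, that of Commd5 and Rpl8, Tnfrsf1a, Atf4, Bax, Cdkn1c and Casp1, and with the mean of the tiled region at Tdo2.

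Signal rose at 1256 promoters and fell at 358 between 0h and 1h in carbohydrate-fed rats (limma, adjusted p under 0.05). With arrays scaled to the same spread the split was 1123 higher and 898 lower, and with quantile normalization 1433 and 701. Camera with a preset correlation called the immediate early list (adjusted p = 3.3e-05), the glucose and amino acid list (adjusted p = 0.000186), the ribosome list (adjusted p = 0.00581) and the acute phase list (adjusted p = 0.00662). Each had adjusted p = 0.804 with an estimated correlation. With array run as a term 5 promoters passed, 0 of them shared with the 1614 calls. The 1614 became 306 without carbohydrate 1h replicate 2, 605, 812 and 950 without carbohydrate 0h replicates 2, 1 and 3, and 899 without carbohydrate 1h replicate 1. It was 3705 with array weights, 5043 with the mean of the tiled region and 835 in the deposited direction of the ratio.

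In ethanol-fed rats at 1h signal rose at Hes1, a repressor downstream of Notch, from 0.01 ± 0.04 to 1.26 ± 0.81 (SD, n = 3 and 3; log2 difference 1.25 ± 0.26 SE, limma adjusted p = 0.0279). It rose at the circadian repressor Bhlhe40 by 1.06 ± 0.15 (adjusted p = 0.00085), the metallothionein promoter of Mt1 and Mt2A by 1.21 ± 0.24 (adjusted p = 0.0204), the lipid transfer protein Stard10 (1.07), Arhgdia, Rasgef1c and Rpl10 (0.87). Insig1, which restrains cholesterol synthesis, rose by 1.02 ± 0.20 (adjusted p = 0.023) and Plin2, a lipid droplet protein, by 0.64 ± 0.15 (adjusted p = 0.0458), the 2 of 40 lipid promoters that passed. Of 35 immediate early promoters 4 rose, Egr1 (1.34 ± 0.28, adjusted p = 0.0279), Junb (1.03 ± 0.22), Btg2 (0.82 ± 0.13) and Ier2 (0.72 ± 0.14), and 11 rose adjusted over the list alone. Of 26 acute phase promoters 2 rose, Itih4 (0.93 ± 0.17) and Itih3 (0.86 ± 0.14), and 10 adjusted over the list alone. None of 43 NF-kB target promoters passed over all promoters, and 5 were higher and 1 lower adjusted over the list alone, with Gadd45b at 0.60, Bcl2l1 at 0.58, the promoter of Daxx, Tapbp and Zbtb22 at 0.61 and Il6 at −0.43. Of these Bcl2l1 and the promoter of Daxx, Tapbp and Zbtb22 turned with array run as a term (−0.06 and −0.21). Signal fell at Cul3, a ubiquitin ligase scaffold, by −0.89 ± 0.14 (adjusted p = 0.00181), at the lymphocyte protease Gzma by −0.68 ± 0.14 (adjusted p = 0.0279) and at the olfactory receptor Olr1564 (−0.60).

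In all, 36 promoters rose and 4 fell in ethanol-fed rats at 1h by limma, with 2363 at an unadjusted p under 0.05 and 727 expected. Camera called the acute phase (adjusted p = 5.01e-07), immediate early (7.78e-07), ribosome (1.17e-06), glucose and amino acid (0.000378), lipid (0.000613) and liver transcription factor (0.00634) lists. These had adjusted p = 0.485, 0.485, 0.485, 0.563, 0.514 and 0.532 with an estimated correlation. Of the risers 21 were shared with those of carbohydrate-fed rats, against 3.11 expected of independent lists, and the differences of both diets correlated at r = 0.449 across promoters, which are not independent of each other. No promoter passed the test of the difference between the diets in this response (limma, 0 of 14540, with 1371 at an unadjusted p under 0.05), where the smallest p values belonged to Otud6b (0.92, adjusted p = 0.086) and Semg1 (−1.14, adjusted p = 0.086). Ethanol 0h replicate 2 and ethanol 1h replicate 1 decided the count, which was 1232 without the former and 1263 without the latter. It was 1 without ethanol 0h replicate 3 and 9 to 11 without any of the other 3 arrays. It was 0 in the fit of the compared arrays alone, 20 with array run as a term, 538 with the mean of the tiled region, 73 with arrays scaled to the same spread, 1325 with array weights and 0 in the deposited direction.

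**Figure D1:**
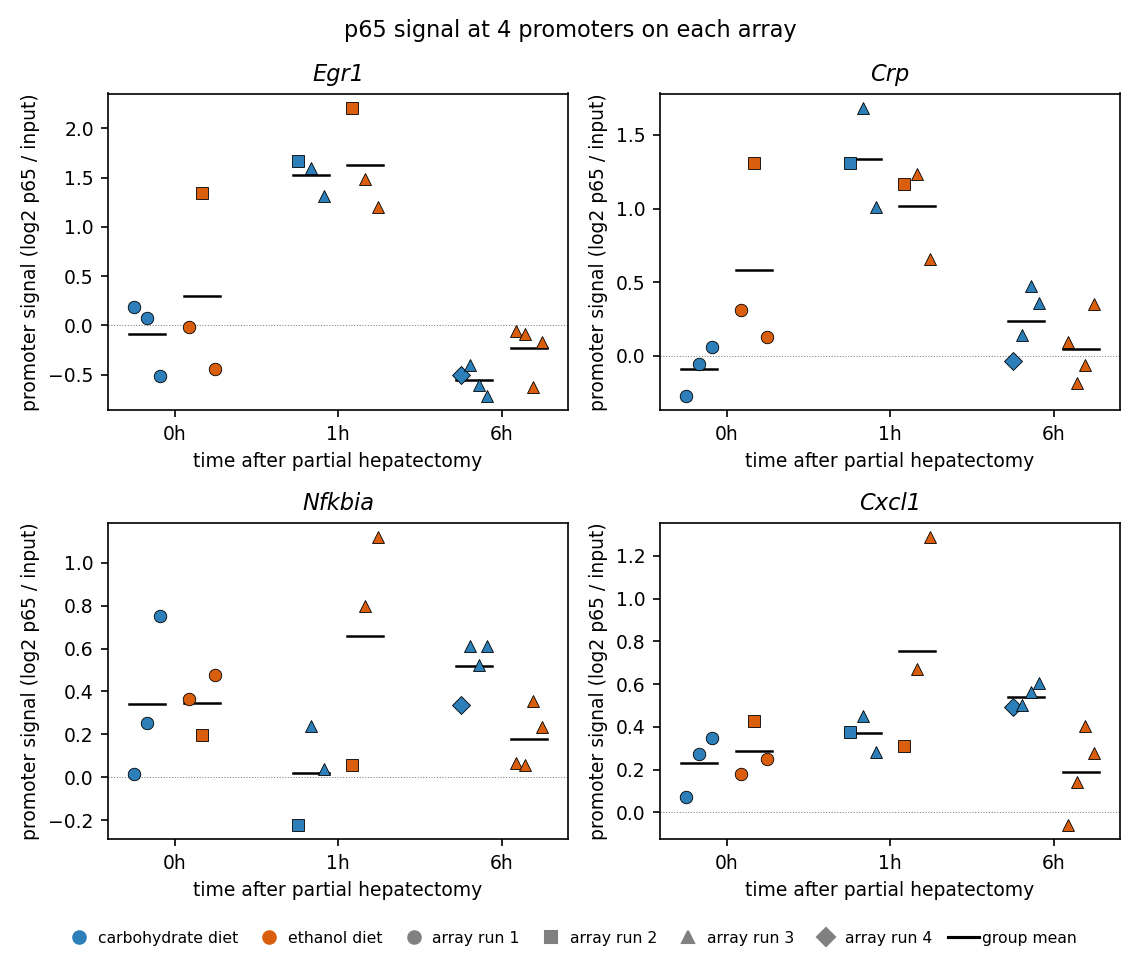
Promoter signal (log2 ratio of p65 to the reference, input per the channel labels) of Egr1, Crp, Nfkbia and Cxcl1 on each of the 20 arrays, by time after hepatectomy and diet, with symbols for the array run and bars for group means. Egr1 was highest at 1h in both diets, and ethanol 0h replicate 2 (run 2) lay apart from the other 0h arrays there.

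At 6h the question was which promoters p65 occupied later in the response. In carbohydrate-fed rats signal rose at Sod2, the mitochondrial superoxide dismutase and a known NF-kB target, from 0.02 ± 0.31 to 0.94 ± 0.10 (SD, n = 3 and 4; log2 difference 0.91 ± 0.15 SE, limma adjusted p = 0.0008). It rose at the chemokine Ccl2 by 0.45 ± 0.13 (adjusted p = 0.0153), at a window on chromosome 10 from 70255382 to 70255852 just upstream of the start at 70256262. It also rose at the apoptosis inhibitor Cflar (0.56) and at the adhesion molecule Sele (0.35), and fell at Xiap (−0.47). As a list the NF-kB targets rose at a smaller share than all promoters (4 of 43 beside 2705 of 14540). The largest rises were at Rin1 (1.19), the adhesion receptor Adgrf5 (1.07 ± 0.16, adjusted p = 0.000657), the melanocortin receptor Mc4r (1.05), Tgap1 (1.03), the promoter of Cfap119 and Rnf40 (1.03) and the olfactory receptors Or9k2 (1.01) and Or2a14 (0.99). Next came Adam4l1 (0.97), a protocadherin alpha promoter (0.97) and Tnr, a matrix protein of the brain (0.96 ± 0.14). Signal fell at Axin1, a scaffold of Wnt signalling, from 0.74 ± 0.10 to −0.26 ± 0.32 (SD, n = 3 and 4; limma adjusted p = 0.00372). Falls were seen too at Rybp (−0.96), at the glutathione transferase Mgst1 (−0.85 ± 0.19, adjusted p = 0.00323), at Dpf1 (−0.77) and at the phospholipase Plcb1 (−0.77). Pgap6, Mms22l, Ap3s2, Rab2a and C1galt1 fell as well.

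Of 43 NF-kB target promoters 4 rose and 1 fell at 6h in carbohydrate-fed rats, 3 and 1 adjusted over the list alone. Of all 14540 promoters 2705 rose and 294 fell, a larger share of rises than in that list. The median difference was 0.125 for the list and 0.147 for all promoters. Shares such as 3 of 15 or 7 of 38 below lie near that of all promoters. Of 35 immediate early promoters 3 rose (Egr3 by 0.71) and none fell. Kupffer cell and macrophage markers rose at 4 of 10, the complement promoter of C1qa and C1qc (0.74), Cd163 (0.51) and Csf1r (0.42) among them, and at 7 adjusted over the list alone. Stellate cell markers rose at 5 of 12 (Col1a1 0.48, Reln 0.46, Dcn 0.46). Lymphocyte and neutrophil markers rose at 3 of 15 (the T cell receptor partner Cd8a 0.82 ± 0.14, adjusted p = 0.0009, Ms4a1 0.71, S100a8 0.56). Sinusoidal endothelial markers rose at 2 of 6 (Tek 0.60, Tie1 0.48), hepatocyte markers at 2 of 12 and cholangiocyte markers at 1 of 7 (Spp1 0.34). In the testis and neuronal comparison list 7 of 38 rose (Tnp1 0.68, Dazl 0.60). Growth factor signalling promoters rose at 8 and fell at 2 of 39 (Met 0.58, Tgfbr1 −0.59), cytokine and JAK-STAT promoters rose at 5 (Il10rb 0.70), ribosome promoters at 5 (Rpl32 0.60), and acute phase promoters at 2. Cell cycle promoters rose at 5 and fell at 1 (0.62 at the promoter of Ap4m1 and Mcm7). Apoptosis promoters did so at 2 and 1, and alcohol and xenobiotic promoters at 3 and 1 (Aldh1b1 0.59, Ahr −0.52). Lipid promoters rose and fell at 3 and 1, glucose and amino acid promoters at 1 and 1 (Cth −0.46), and 1 liver transcription factor rose. The balance turned with arrays scaled to the same spread for the lipid (2 and 10), cell cycle (3 and 6) and liver transcription factor (0 and 5) lists. No list was called by camera, with adjusted p = 0.0773 for the Kupffer cell list and 0.0989 for the stellate cell list, while 9 lists were called with array run as a term. With that term the direction turned at Cflar, Dazl and the promoter of Cfap119 and Rnf40, and with the mean of the tiled region at Egr3, Col1a1, Reln, Dcn and Tie1.

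In total 2705 promoters rose and 294 fell between 0h and 6h in carbohydrate-fed rats (limma), and the median over all promoters was 0.15. A set of 1293 promoters of olfactory, vomeronasal and taste receptors was formed after the named genes were seen. Of these 643 rose and none fell, with a median of 0.36 beside 0.13 for the others (camera p = 0.111 with an estimated correlation). The direction of this rise rests on the turned sign of the ratio, and no value in the deposited direction is given here for the set. With arrays scaled to the same spread the split was 2080 and 805, with the mean of the tiled region 609 and 805 and a median over all promoters of −0.02. With array run as a term 52 promoters passed, 10 of the calls among them. The count was 507, 1084 and 1928 without carbohydrate 0h replicate 2, carbohydrate 0h replicate 1 and carbohydrate 6h replicate 4, 7277 with array weights and 715 in the deposited direction.

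In ethanol-fed rats at 6h signal rose at a protocadherin alpha promoter (0.85), the chromatin protein Morf4l1 (0.78), the vomeronasal receptor Vom2r6 (0.74), Mat2b, a subunit of the enzyme that makes S-adenosylmethionine (0.66), and Clca2 (0.65). Or6c1, Ly49s3 and Vom2r67 rose as well. It fell at Axin1 by −1.26 ± 0.23 (limma adjusted p = 0.0156), from 0.86 ± 0.33 to −0.40 ± 0.21 (SD, n = 3 and 4). Falls were also seen at Pianp (−1.53), Negr1 (−1.53), Pgap6 (−1.24), Dpf1 (−1.04), the repressor Bcl6 (−0.98), Zfp330 (−0.93), dopa decarboxylase, Ddc (−0.92), and methionyl-tRNA synthetase, Mars1 (−0.91). Ahr fell by −0.58 ± 0.14 (adjusted p = 0.0403) and Elovl6, which elongates fatty acids, by −0.82 ± 0.20 (adjusted p = 0.0403), each the only member of its list to fall. Dcn, a stellate cell marker (0.49 ± 0.12, adjusted p = 0.0386), and the translation factor Eif3e (0.59) rose. No immediate early promoter passed over all promoters, and 8 were lower adjusted over the list alone, with the promoter of Flot1 and Ier3 at −0.79, Zfp36 at −0.59, Jun at −0.45 and Fos at −0.42. No NF-kB target promoter passed, and 2 were lower adjusted over the list alone.

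The ethanol 6h arrays gave 54 promoters that rose and 91 that fell against 0h (limma, with 3021 at an unadjusted p under 0.05). Camera called the immediate early list lower (adjusted p = 0.00242, and 0.825 with an estimated correlation). It also called the cytokine, cell cycle, alcohol, lipid, glucose and liver transcription factor lists lower and the Kupffer and stellate cell lists higher, at adjusted p from 0.0321 to 0.0415, and with an estimated correlation the lowest adjusted p of any list was 0.560. With quantile normalization the split was 408 higher and 413 lower. Of the risers 42 were shared with carbohydrate-fed rats (10.1 expected of independent lists), and of the fallers 27 (1.84 expected), with r = 0.600 across promoters. No promoter passed the test of the difference between diets at 6h against 0h (limma, 0 with 1954 at an unadjusted p under 0.05), where the smallest p values lay at Nfyb (0.66) and the promoter of Cfap119 and Rnf40 (−1.09, adjusted p = 0.293). The count of 145 fell to 0 without ethanol 0h replicate 2, ethanol 6h replicate 2 or ethanol 6h replicate 3. It was 2, 39 and 79 without ethanol 0h replicate 1 and ethanol 6h replicates 1 and 4, and 1297 without ethanol 0h replicate 3. With array run as a term it was 574 (29 of the calls among them), with scaling to the same spread 760 and with quantile normalization 821. It was 52 with slide as a random block, 1621 with array weights, 8 in the fit of the compared arrays alone, 7 in the deposited direction and 0 with the mean of the tiled region.

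Because no run held both 0h and 6h arrays, 6h was also set against 1h inside the third run, a comparison chosen after the data were seen, as were the genes named from it. It held 2 arrays of carbohydrate 1h, 3 of carbohydrate 6h, 2 of ethanol 1h and 4 of ethanol 6h. Of all 14540 promoters 2739 rose and 779 fell from 1h to 6h in carbohydrate-fed rats. In ethanol-fed rats 1562 rose and 3577 fell, and the list counts below stand beside these shares. Of 35 immediate early promoters 15 fell and 1 rose from 1h to 6h in carbohydrate-fed and 24 fell and none rose in ethanol-fed rats, with 17 and 26 falls adjusted over the list alone. Camera with an estimated correlation did not call the list (adjusted p = 0.249 and 0.263). Egr1 fell by −2.03 ± 0.15 (limma adjusted p = 6.07e-12) and −1.58 ± 0.14 (adjusted p = 2.46e-09), and Jun by −0.90 in carbohydrate-fed and Junb by −1.41 ± 0.17 in ethanol-fed rats. Acute phase promoters fell at 6 and rose at 3 of 26 in carbohydrate-fed rats, with Crp at −1.02 ± 0.19, and fell at 19 in ethanol-fed rats, with Itih4 at −1.01 and Alb at −0.83. Lipid promoters fell at 8 and 25 of 40 and rose at 2 and 1, with Insig1 at −1.33 ± 0.15 and −1.55 and the carnitine transferase Cpt1a at −1.17 in ethanol-fed rats. Of 43 NF-kB target promoters 6 rose and 5 fell in carbohydrate-fed rats, a smaller share of rises and a larger share of falls than among all promoters. The risers there included Sod2 (0.65 ± 0.17), Vcam1 (0.47), Ccl20 (0.48) and Nfkbia (0.44 ± 0.15). With the mean of the tiled region Nfkbia turned there (−0.06). In ethanol-fed rats 15 of 43 fell and 2 rose, with falls at Irf1 (−0.94), Bcl3 (−0.86), Cxcl1 (−0.79 ± 0.16) and Nfkbia (−0.78 ± 0.14, adjusted p = 6.86e-05). Ribosome promoters fell at 4 and 23 of 40, glucose and amino acid promoters at 12 and 22 of 30, and cytokine promoters at 6 and 16 of 36. In carbohydrate-fed rats the testis and neuronal comparison list rose at 7 and fell at 1 of 38, and in ethanol-fed rats it rose at 2 and fell at 5. Of cell type markers, those of hepatocytes fell at 2 and 7 of 12. In carbohydrate-fed rats lymphocyte and neutrophil markers rose at 4 of 15, stellate cell markers at 3 of 12 and cholangiocyte markers at 2 of 7. For such small lists these shares, and the 7 of 38 of the comparison list, lie near that of all promoters. In ethanol-fed rats each of these 3 marker lists had 2 that rose and 1 that fell. Kupffer cell markers rose at 1 and 2 of 10, and 1 fell in carbohydrate-fed rats. Receptor promoters rose at 871 of 1293 and fell at none in carbohydrate-fed rats and rose at 622 and fell at 3 in ethanol-fed rats. The median difference was 0.45 and 0.31 beside 0.08 and −0.12 for other promoters (camera p = 0.0514 and 0.0354 with an estimated correlation).

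**Figure D2:**
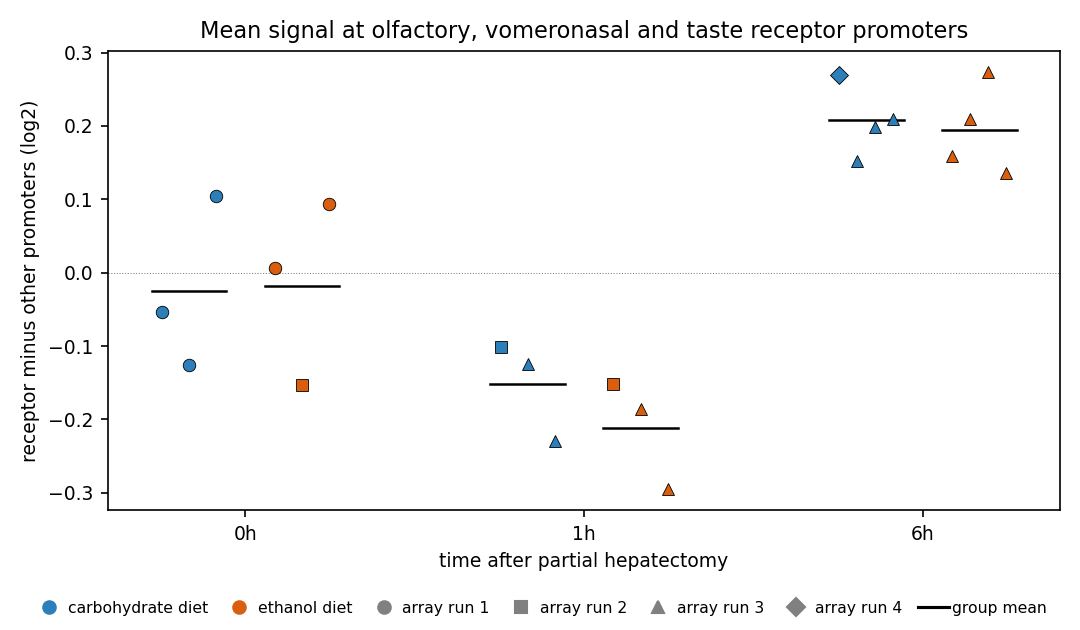
Mean promoter signal of olfactory, vomeronasal and taste receptors minus that of the other promoters (log2) on each of the 20 arrays, by time and diet, with symbols for the array run and bars for group means. All 8 arrays of 6h lay between 0.14 and 0.27, and all 6 of 1h between −0.30 and −0.10. These directions rest on the turned sign of the ratio.

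Across all promoters 2739 rose and 779 fell from 1h to 6h in carbohydrate-fed rats and 1562 rose and 3577 fell in ethanol-fed rats inside this run (limma). With slide as a fixed term the counts were 921 and 435, and 551 and 2030. Camera called the immediate early list lower in both diets (adjusted p = 7.64e-11 and 2.74e-10, and 0.249 and 0.263 with an estimated correlation). It called likewise the acute phase (0.000324 and 5.12e-06, then 0.495 and 0.353), lipid (1.91e-05 and 0.000171, then 0.249 and 0.263) and glucose and amino acid lists (8.11e-08 and 0.00021, then 0.257 and 0.411). It called the liver transcription factor list lower too (0.000257 and 0.00021, then 0.257 and 0.263), the cytokine list (0.00654 and 0.0123, then 0.495 and 0.411), the alcohol and xenobiotic list (0.0466 and 0.0116, then 0.771 and 0.411), the cell cycle list in ethanol-fed rats (0.0179, then 0.469) and the lymphocyte and neutrophil markers higher in ethanol-fed rats (0.0329, then 0.411). The ribosome list, a comparison list, was also called lower (0.00175 and 0.00021, then 0.614 and 0.411), and the NF-kB targets were not (0.215 and 0.0665, then 0.771 and 0.583). The carbohydrate count of 3518 was 904 without carbohydrate 1h replicate 3 and 2154 without carbohydrate 6h replicate 4, and the ethanol count of 5139 was 2831 without ethanol 1h replicate 3 and 8117 with the mean of the tiled region.

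**Figure D3:**
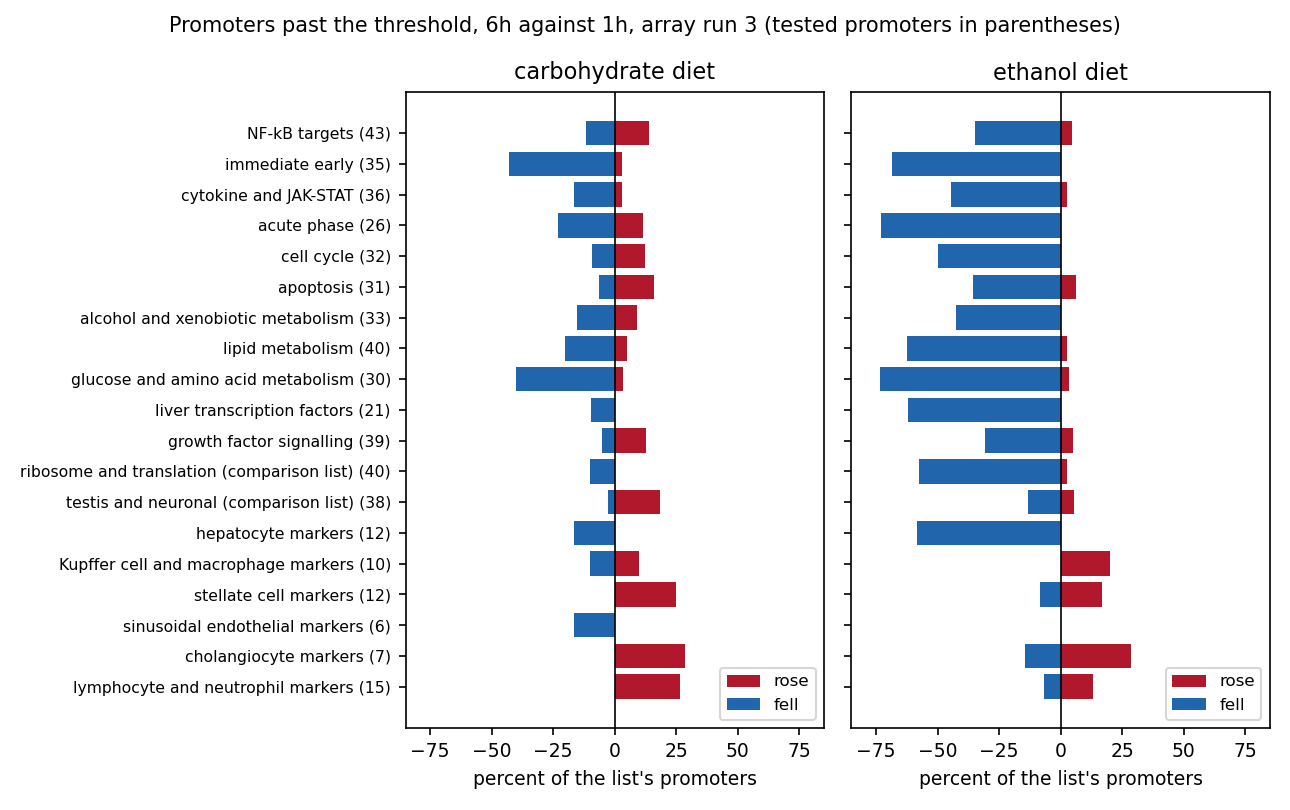
Number of promoters of each fixed list that rose (right of 0) or fell (left of 0) from 1h to 6h inside the third array run, as percent of the list's tested promoters, for carbohydrate-fed and ethanol-fed rats (limma, adjusted p under 0.05). Immediate early promoters fell at 15 and 24 of 35.

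The central comparison set ethanol against carbohydrate at each time. Over all 20 arrays no promoter passed at 0h, 1h or 6h or over all times (limma, 0 of 14540 each, with 1106, 1189, 1590 and 442 at an unadjusted p under 0.05 and 727 expected). At 1h the smallest p values belonged to Otud6b, a deubiquitinase (0.65, adjusted p = 0.133), the glutamate transporter Slc1a1 (0.66, adjusted p = 0.133) and the promoter of Cdc40 and Wasf1 (0.59). Below 0 they belonged to Semg1 (−0.69, adjusted p = 0.157), the receptor Tnfrsf14 (−0.55) and Btnl7 (−0.48). Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm, had 0.66 ± 0.54 in ethanol-fed and 0.02 ± 0.23 in carbohydrate-fed rats at 1h (SD, n = 3 each; difference 0.64 ± 0.20 SE, adjusted p = 0.433). The window lay on chromosome 6 from 75733672 to 75734122. At 6h it had 0.18 ± 0.14 and 0.52 ± 0.13 (SD, n = 4 each; difference −0.34 ± 0.17, adjusted p = 0.457). The chemokine Cxcl1 differed by 0.39 ± 0.17 at 1h (adjusted p = 0.571) and −0.35 ± 0.15 at 6h (adjusted p = 0.44), and Nfkb2 by 0.35 ± 0.13 at 6h against 0h in carbohydrate-fed rats (adjusted p = 0.0515; −0.01 with the mean of the tiled region). At 0h the smallest p values lay at Pbld1 (0.92 ± 0.18, adjusted p = 0.301) and Smad2, a mediator of transforming growth factor signals (−0.62, adjusted p = 0.622). At 6h they lay at Spink13 (0.54) and complement C9 (0.41), and below 0 at Pigk (−0.53), Cd8a (−0.57) and Nkain4 (adjusted p = 0.429 each), and over all times below 0 at Or6f2 (−0.28). Tnfaip3 and Icam1 had no named promoter among those tested. Names came from the peak lists, so these genes may lie among the 1411 unnamed promoters or outside the tested ones.

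Adjusted over the list alone, a few promoters passed between the diets. At 1h these included Ahr (0.66, adjusted p = 0.005) and Cp (0.45, adjusted p = 0.0332), both higher in ethanol-fed rats. At 6h they were Cd8a (−0.57, adjusted p = 0.00239) and the ribosomal Rpl32 (−0.40, adjusted p = 0.0248), and over all times the cholangiocyte keratin Krt19 (−0.20, but 0.01 with the mean of the tiled region). Camera called the acute phase list higher in ethanol-fed rats at 1h (adjusted p = 0.0196, and 0.883 with an estimated correlation). Over all times it called the acute phase (0.0147), alcohol and xenobiotic (0.0125) and liver transcription factor lists (0.0465), where no list had an adjusted p below 0.755 with an estimated correlation. With the mean of the tiled region and the preset correlation camera called 5 lists at 0h, 7 at 1h, 0 at 6h and 8 over all times. On simulated differences at these group sizes limma recovered 25% and 32% of promoters changed by 0.4 log2 at 1h and 6h. Of those changed by 0.8 it recovered 96% and 97%. The simulated noise was independent between promoters and arrays, while the real arrays of a slide or run were correlated. Recovery on the real arrays is therefore not known. Array weights gave 10, 2 and 2751 promoters at 0h, 1h and 6h and 2259 in the test of the diets at 6h against 0h, array run as a term gave 47 at 1h, and slide as a random block gave 6 at 1h. The fit of the compared arrays alone gave 12 at 6h. Without ethanol 1h replicate 1 there were 183 at 1h and 92 in the test of the diets at 1h against 0h. Without carbohydrate 0h replicate 3 there were 28 in that at 6h, and without ethanol 0h replicate 1 there were 4 at 0h.

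Inside the third run alone, chosen after the data were seen, 319 promoters were higher and 39 lower in ethanol-fed than in carbohydrate-fed rats at 1h (limma, 2 arrays each), and 1 was higher and 261 lower at 6h (3 arrays against 4). At 1h the higher ones included Nfkbia (0.82 ± 0.16, adjusted p = 0.0048), the interleukin 6 receptor Il6r (0.79 ± 0.15, adjusted p = 0.0048) and Bcl3, an NF-kB cofactor (0.54 ± 0.13, adjusted p = 0.0193). Others were Ahr (0.85 ± 0.14, adjusted p = 0.00221), the phosphatase subunit Ppp6r1 (1.11 ± 0.16, adjusted p = 0.000263) and the cannabinoid receptor Cnr1 (0.85). Semg1 (−0.76 ± 0.13) and the T cell receptor chain Cd3e (−0.58 ± 0.15) were lower. Of 43 NF-kB target promoters 2 were higher, 3 adjusted over the list alone, and no list reached an adjusted p below 0.924 with an estimated correlation. At 6h the lower ones included Cenpn, a centromere protein (−0.77 ± 0.12, adjusted p = 0.00469), Mc4r (−0.74), Rin1 (−0.69), the promoter of H4c14 and Hist2h3c2 (−0.66), the phosphatase Dusp2 (−0.45 ± 0.10), connective tissue growth factor, Ccn2 (−0.42 ± 0.11), and Cd8a (−0.61 ± 0.13). None of the NF-kB targets passed at 6h, 2 immediate early and 2 acute phase promoters were lower, and Or4e2 was higher (0.42 ± 0.11).

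These counts rested on few arrays. At 1h the count of 358 was 362 with slide as a fixed term, 56 and 4 without carbohydrate 1h replicates 2 and 3, and 1175 and 16 without ethanol 1h replicates 2 and 3. It was 1475 with the mean of the tiled region, 70 with quantile normalization and 0 with all 20 arrays. At 6h the count of 262 was 0 with slide as a fixed term, with the mean of the tiled region, with all 20 arrays and without carbohydrate 6h replicate 2. It was 10, 2, 3 and 3 without carbohydrate 6h replicates 3 and 4 and ethanol 6h replicates 1 and 2, 1031 without ethanol 6h replicate 3, 17 with scaling to the same spread and 81 with quantile normalization. The median over all promoters was −0.13 at 6h. Of the 319 promoters higher at 1h, 61.4% were also higher in ethanol on the slide of the second run, where 46.3% of all promoters were.

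The change from 1h to 6h differed between the diets inside the third run at 83 promoters in the positive and 1532 in the negative direction (limma, median over all promoters −0.19). Nfkbia moved by −1.22 ± 0.20 relative to carbohydrate-fed rats (adjusted p = 0.000638), since its mean went from 0.14 to 0.58 there and from 0.96 to 0.18 in ethanol-fed rats. Il6r (−1.09 ± 0.19, adjusted p = 0.00121), Cxcl1 (−0.98 ± 0.23, adjusted p = 0.00756), Irf1 (−0.61), Traf2 (−0.55) and Bcl3 (−0.61) were lower too. In total 5 of 43 NF-kB target promoters were lower and none higher, a share no larger than that of the testis and neuronal comparison list (5 of 38 lower and 1 higher) and near that of all promoters (1532 of 14540). With the mean of the tiled region Nfkbia still passed (−0.41), and Irf1, Traf2 and Bcl3 did not. The immediate early list had 7 of 35 lower (Ccn1 −0.84 ± 0.20, Fos −0.76 ± 0.18), the acute phase list 6 of 26 (Serping1 −0.74, Apcs −0.68) and the cytokine list 6 of 36 lower and 1 higher (Il6st −0.69, Il10 0.62). The alcohol list had 6 of 33 (Ahr −0.94 ± 0.18), the apoptosis list 5 of 31 (Casp2 −0.90 ± 0.19), and the lipid, cell cycle and ribosome lists 4 each (Cpt1a −0.83 ± 0.20). Growth factor signalling had 4 of 39 lower and 1 higher, liver transcription factors and hepatocyte markers 1 lower each, glucose and amino acid metabolism 1 higher, and the other markers none. No list was called by camera, with adjusted p of at least 0.938 with an estimated correlation. The count of 1615 was 824 with slide as a fixed term, 954 with scaling to the same spread, 535 with quantile normalization, and 0 with all 20 arrays. It was 328 and 341 without ethanol and carbohydrate 1h replicate 3, 791, 926, 981 and 1057 without carbohydrate 6h replicate 4, ethanol 6h replicates 1 and 2 and carbohydrate 6h replicate 3, and 2561 without ethanol 1h replicate 2.

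The authors' peak lists gave the same comparisons by count. Ethanol 1h arrays carried 7913 ± 1793 peaks and carbohydrate 1h arrays 5430 ± 589 (SD, n = 3 each; ratio 1.46, exact permutation test, two-sided, p = 0.2, where 0.1 is the smallest possible, BH-adjusted 0.411 over 9 comparisons). On each slide that held both diets at 1h the ethanol array carried more peaks (5916, 8435 and 9387 beside 4881, 5358 and 6052). The permutation test did not use this pairing by slide. From 1h to 6h peaks in ethanol-fed rats went to 4633 ± 971 (n = 4; ratio 0.586, exact p = 0.0286, the smallest possible, BH-adjusted 0.257). Carbohydrate arrays carried 4340 ± 1619 at 0h and 5784 ± 1398 at 6h (n = 3 and 4; exact p = 0.229), and ethanol arrays 4666 ± 1225 at 0h. No comparison passed after adjustment. Across the 20 arrays the number of peaks went with the correlation between neighbouring probes of the array (Pearson r = 0.938, permutation p = 1e-05, the smallest possible; Spearman rho = 0.842, p = 2e-05). The relation held inside the third run (r = 0.940, 11 arrays, permutation p = 5e-05) and without the 2 arrays farthest from the median (r = 0.914).

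**Figure D4:**
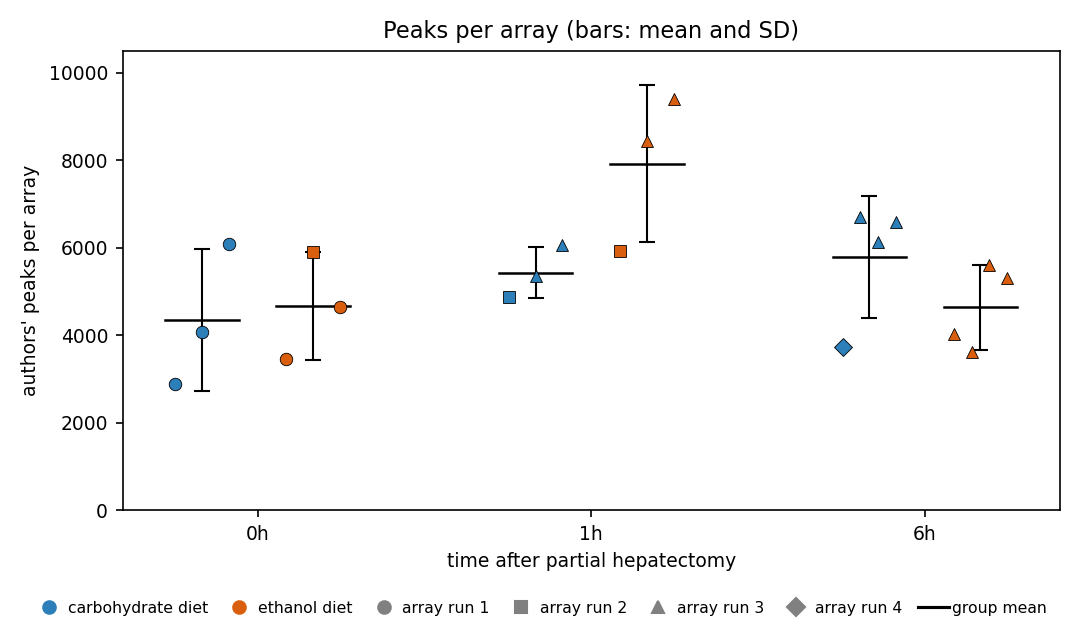
Number of the authors' peaks on each array by diet and time, with group means and SD, and symbols for the array run. The 3 ethanol 1h arrays carried 5916 to 9387 peaks and the carbohydrate 1h arrays 4881 to 6052.

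Genes bound on at least 2 arrays of a group numbered 2960, 4141 and 5688 at 0h, 1h and 6h in carbohydrate-fed rats and 2836, 5973 and 4341 in ethanol-fed rats. Had each array's peaks fallen on genes independently, 2548, 3351 and 6037, and 2778, 5476 and 4148 would be expected, so that by this rule the carbohydrate 6h count lay below that value and the ethanol 0h count near it. A peak on every array of the group was listed for more genes than expected throughout, 842, 1644 and 1669 against 257, 440 and 175, and 579, 2250 and 966 against 311, 1046 and 67.2. Of the genes bound in either diet, 24.3%, 40.3% and 49.5% were bound in both. Independent lists would share 585, 1723 and 1720 genes, and 1134, 2906 and 3322 were shared. Of 11511 genes bound in any group, 3056 (26.5%) had the same pattern over the 3 times in both diets, and 25 of 100 random assignments of the arrays to the diets gave as few (median 3249). Arrays of 1 group shared more of their bound genes than arrays of different groups (mean Jaccard index 0.350 against 0.223, permutation p = 1e-05, one-sided, the smallest possible), also without pairs of the same run (0.313 against 0.201, p = 4e-05). Pairs of different groups on the same slide shared as much as those of 1 group (0.349, 11 pairs), and pairs of different groups in the same run had 0.271 (53 pairs), which the permutation of group labels leaves out of account.

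Genes with a peak on every array of 1 diet and none of the other numbered 272 for ethanol and 56 for carbohydrate at 1h, 77 and 125 at 0h, and 10 and 49 at 6h. At 1h those of ethanol included Pigr, which carries immunoglobulin A into bile (promoter difference 0.65 ± 0.21 SE, limma adjusted p = 0.433), Tgfbrap1 (0.62 at the promoter it shares with C9h2orf49), Wasf1 (0.59), Ugt2a3 (0.58) and Nampt, which makes NAD (0.56). Those of carbohydrate included Tnfrsf14 (−0.55), Dlgap4 (−0.54) and Btnl7 (−0.48). At 0h Klhl26 (0.77) and the chemokine Ccl5 (0.47) belonged to ethanol and C1galt1 (−0.56) and the histone acetyltransferase Hat1 (−0.44) to carbohydrate, and at 6h Lefty2 (0.22) to ethanol and Grwd1 (−0.46) and Fbxw2 (−0.43) to carbohydrate. Other assignments of the same arrays gave as many such genes in 2 of 10 at 1h (highest other 518, against 328), 5 of 10 at 0h (highest other 416, against 202) and 4 of 35 at 6h (highest other 153, against 59), the true one included. None of these promoters passed limma's test between the diets.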

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

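Of the tests in this part, that of stronger enrichment on the ethanol 1h arrays was chosen before its result was seen, and the others, with the comparisons inside the third array run and the counts over other splits of the arrays, were chosen only after.

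Inside the third run the change from 1h to 6h differed between the diets by limma's test of the difference itself at 1615 promoters. Relative to carbohydrate-fed rats the change in ethanol-fed rats was −1.22 log2 at Nfkbia, −1.09 at Il6r, −0.98 at Cxcl1, −0.61 at Irf1, −0.55 at Traf2 and −0.61 at Bcl3. It was −0.84 at Ccn1, −0.76 at Fos, −0.74 at Serping1, −0.68 at Apcs, −0.69 at Il6st, −0.94 at Ahr, −0.90 at Casp2 and −0.83 at Cpt1a, and 0.62 at Il10. The fit of all 20 arrays gave 0 such promoters for the diets at 1h or 6h against 0h.

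A single array stood apart from the other 3 of its group, by the gap to its neighbour over the range of the group, for 2 of 8 array measures and 10 of 179 named promoters in carbohydrate 6h (5.59%). This was so for 0 of 8 and 13 of 179 in ethanol 6h (7.26%), and chance gives about 1 in 20 groups. Carbohydrate 6h replicate 1, the only array of its run, had the fewest peaks of its group at FDR up to 0.05 (gap share 0.922) and the longest peaks (0.884). It had the highest signal at Aldh1b1 (0.846) and the lowest at Bax (0.834), Pianp (0.979), Pigk (0.889), Ppp6r1 (0.866), Rpl32 (0.834) and Serping1 (0.859). Replicate 4 of that group was highest at C1qa and C1qc (0.912), replicate 3 at Elovl6 (0.858) and replicate 2 at Hat1 (0.851). In ethanol 6h replicate 4 was highest at Actg1 (0.934), Errfi1 (0.844), Spp1 (0.841) and Tnfrsf1a (0.871). Replicate 3 was highest at Cpt1a (0.839), Insig1 (0.857) and Nkain4 (0.909) and lowest at Axin1 (0.887) and Zfp36l1 (0.871). Replicate 1 was lowest at Commd5 and Rpl8 (0.886) and highest at Dlgap4 (0.839), and replicate 2 was lowest at Junb (0.911) and highest at Nampt (0.880).

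Changes between the operation and the later times may follow the array run, because 5 of the 6 arrays of 0h made up a run of their own. With array run as a term 0.917% of the calls of the 4 comparisons with 0h kept their call and direction, but that fit rests on 1 array of 0h outside the first run, so for these calls run and time cannot be told apart. The 0h arrays came from the lobes taken out and the later ones from the remnant lobes, so lobe and time cannot be told apart either. The 4 animals with 2 arrays each gave a 0h and a later array, a pairing that the main fit left out. For immediate early promoters, lower at 6h than at 1h, the values argue against array run. Inside the third run the median of the list lay −0.305 log2 from that of all promoters in the diet where it was nearer to 0. By promoter signal the direction of this fall rests on the turned sign of the ratio. The authors' peaks do not use that turn. By them a larger share of immediate early genes was bound at 1h than at 6h in both diets. In the deposited direction, which also took other windows, the list lay −0.05 log2 from other promoters at 1h and 0.05 at 6h. With the turned sign these values give a fall as well. Signal that follows active promoters of any kind, rather than p65 sites, stays open there, since the median of the NF-kB target list minus that of the ribosome list was 0.164 for 6h against 1h. Time after the operation stays open beside it and was not tested apart from it.

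The library labelled ethanol 0h replicate 2 shares its animal number with the ethanol 1h array of its slide and stood with the 1h arrays: at promoters higher at 1h than at 6h inside the third run it lay 107.8% of the way from the other 0h arrays to the 1h arrays of that run, where the other 0h arrays, which set the start of that scale, lay between −20.7 and 11.7%. A 1h sample under a 0h label is a candidate explanation, because at promoters lower at 1h it lay at 65.4%, which is 9.04 points below the nearer of the 1h arrays of its slide (74.4 and 75.0%), though the other 0h arrays spread from −50.2 to 40.9% there. A slide effect is another, since at 4219 promoters with little difference between 1h and 6h its mean r with the 1h arrays of its slide was 0.642, against 0.145 with the 0h arrays of the first run, a difference of 0.497. The 1h minus 0h difference inside this slide correlated with that of the other ethanol arrays at r = −0.0446 across promoters, but those other arrays differ in run as well as time, so this decides nothing. A wrong label, a swap, the slide, the shared animal and an early response in this animal all stay open.

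The ethanol 1h arrays of the third run carried the most peaks of all arrays (8435 and 9387), and there 319 promoters were higher and 39 lower than in carbohydrate 1h. The number of peaks followed the correlation between neighbouring probes over the 20 arrays (r = 0.938), which was highest on these 2 arrays (0.540 and 0.595), but more binding raises that correlation too, so less noise as the cause was left undecided. Stronger enrichment on these arrays as a whole was undecided as well, since the diet difference correlated at r = 0.171 across promoters with the mean signal of the other runs. Diet stays open as well, because the difference on the slide of the second run correlated with that inside the third run at r = 0.114 across promoters, too low to show that it recurs and too high to exclude it. With 2 arrays of each diet in the third run these explanations cannot be told apart.

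Other splits of the same arrays were fitted for each count. For 6h against 0h 1 of 35 splits, the true one, gave as many promoters as 2999 in carbohydrate-fed rats (highest other 436). The same held for 145 in ethanol-fed rats (highest other 2). That share is under 0.05 and the smallest that 35 splits allow. It was not adjusted for the several counts tried, so it does not exclude chance. The 145 also fell to 0 without ethanol 0h replicate 2. The true split parts the first array run from the later runs, but for ethanol 0h replicate 2, so it does not exclude array run either. For 1h against 0h the 10 splits are too few for a share under 0.05 (1614 in carbohydrate, 1 split with as many and highest other 2; 40 in ethanol, 5 splits and highest other 418). The same holds between the diets at 0h (0, highest other 1 of 10 splits) and 1h (0, highest other 374). Where the true split gave 0 every split gives at least as many, so the counts for the diets at 6h (35 splits, highest other 0) and, with 100 splits drawn, over all times (highest other 81), for the difference in the 1h change (highest other 720) and for that in the 6h change (highest other 1) decide nothing about chance. Other splits called up to 374 and 720 promoters where the true one called 0, and what those splits follow was not tested. Inside the third run 2 of 35 splits gave at least the 262 promoters between the diets at 6h (highest other 585), so chance was not excluded.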

How the results depend on the processing

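The deposited direction of the ratio, the fits of single runs and the tests inside the third run were chosen only after the data were seen. For each value below the cause was not tested unless the setting itself gives it. The deposited direction took other windows besides the other sign. The sign alone turns each difference around and leaves a two-sided count as it is, so these counts differ through the windows. Between the diets, counts over all times stayed at 0 under every setting run. At 0h they were 1 with scaling and with quantile normalization, 10 with array weights and 0 to 4 with 1 array left out. At 1h they were 6 with slide as a random block, 47 with array run as a term, 2 with array weights, 358 in run 3 alone and 0 to 183 with 1 array left out. At 6h they were 12 with the compared arrays alone, 2751 with array weights and 262 in run 3 alone. The difference between diets in the 1h change had 2 promoters with scaling, quantile normalization, array run and array weights, 3 with slide and 0 to 92 with 1 array left out. That in the 6h change had 2259 with array weights and 0 to 28. For 1h against 0h in carbohydrate-fed rats (1614) there were 5043 with the region mean, 5 with array run, 3705 with array weights, 835 in the deposited direction and 306 to 1330 with 1 array left out. For 6h against 0h (2999) there were 1414, 52, 7277, 715 and 507 to 4165 under the same settings. For 1h against 0h in ethanol-fed rats (40) there were 538 with the region mean, 73 with scaling, 20 with array run, 0 with the compared arrays alone and in the deposited direction, 1325 with array weights and 1 to 1263 with 1 array left out. For 6h against 0h (145) there were 0 with the region mean, 760 with scaling, 821 with quantile normalization and 52 with slide. There were 574 with array run, 8 with the compared arrays alone, 1621 with array weights, 7 in the deposited direction and 0 to 1297. In all 127 such counts stayed within 1.5 times the reported one and 68 did not. With the replicate number as a block they were 119 and 381 in ethanol-fed rats at 1h and 6h and 1 in the difference of the diets at 1h. The numbers were not taken to pair the arrays, since no label says that they do and 22 of 46 same-numbered pairs of different groups, not all, correlated above 0.1 in their deviations (mean r 0.0666). Pairs of different numbers had a mean r of −0.0263, with 37 of 120 above 0.1. Of 20 arrays 12 correlated best with an array of their own number. This hint of pairing goes in part with shared slides. At 1h same-numbered arrays of the diets lay on the same slide, with r of 0.504, 0.191 and 0.280 for replicates 1, 2 and 3.

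Inside the third run, the diet count at 1h (358) was 0 with all 20 arrays, 1475 with the region mean, 70 with quantile normalization, 34 in the deposited direction and 4 to 1175 with 1 array left out. At 6h (262) it was 0 with slide as a fixed term, all 20 arrays or the region mean, 17 with scaling, 81 with quantile normalization, 12 in the deposited direction and 0 to 1031. From 1h to 6h the carbohydrate count (3518) was 1356 with slide, 278 in the deposited direction and 904 to 3054. The ethanol count (5139) was 2581 with slide, 8117 with the region mean, 819 in the deposited direction and 2831 to 5012. Their difference (1615) was 824 with slide, 0 with all 20 arrays, 954 with scaling, 535 with quantile normalization, 122 in the deposited direction and 328 to 2561.

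With peaks at FDR up to 0.05 the genes bound at 0h, 1h and 6h numbered 703, 1509 and 2061 in carbohydrate-fed and 605, 2874 and 1529 in ethanol-fed rats. With a peak required on every array they numbered 842, 1644 and 1669 (257, 440 and 175 expected of independent arrays), and 579, 2250 and 966 (311, 1046 and 67.2), and on any array 7880, 7734 and 8617, and 8791, 9893 and 7691, as fewer or more peaks count by construction. With 1 array left out, genes bound ranged from 1368 to 1894 and 2207 to 2909 at 0h and 1h in carbohydrate-fed and from 1224 to 1446 and 2913 to 4595 in ethanol-fed rats. Genes with the same pattern in both diets numbered 1359 at FDR up to 0.05 and 1158 with a peak on every array. The ratio of peaks of ethanol to carbohydrate at 0h ran from 0.920 to 1.34 with 1 array left out (0.932 without ethanol 0h replicate 2). That of 6h to 0h in ethanol-fed rats ran from 0.879 to 1.15 (1.04, 1.07 and 1.15 without ethanol 6h replicates 1 and 2 and ethanol 0h replicate 2), with 1.06 at FDR up to 0.05. The ratio of 6h to 1h in carbohydrate-fed rats was 0.959 at FDR up to 0.05. The other 71 ratios kept their side of 1. None of their tests passed after adjustment, which these group sizes do not allow. The 4 other measures of shared peaks gave differences of 0.104 to 0.116 against 0.126. NF-kB targets lay 0.00401 above other promoters with the region mean (exact sign test p = 0.503), above on all 6 arrays of 1h and below on all 8 of 6h as before, and with the opposite signs in the deposited direction, as for the immediate early list at 1h (above on 0 of 6 arrays) and 6h (7 of 8). Of 23 camera calls 0 held with an estimated correlation, and the region mean with the preset correlation gave 49. Between the diets the region mean gave 5 lists at 0h, 7 at 1h and 8 over all times, in place of 0, 1 and 3. It gave 3 in place of 0 for the difference of the diets at 1h, and 0 as before between the diets at 6h. With array run as a term 9 lists in place of 0 were called for 6h against 0h in carbohydrate-fed rats and 8 in place of 9 in ethanol-fed rats. For 1h against 0h it was 1 in place of 4 and 1 in place of 6, for the difference of the diets at 1h 3 in place of 0, and over all times 0 in place of 3.

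For comparisons with 0h, array run as a term rests on ethanol 0h replicate 2, so the turns under it cannot tell run from time. With array run as a term the 1h change in carbohydrate-fed rats turned at the promoter of Esrp2 and Pla2g15 (−0.28), Igfbp1 (−0.19), Zfp36l1 (−0.50), Gadd45g (−0.36), Junb (−0.089), Bcl2l1 (−0.13), Irf1 (−0.30), Gadd45b (−0.12) and Hpd (−0.083). It turned too at Dapk3, Eef2 and Pias4 (−0.47), Commd5 and Rpl8 (−0.28), Tnfrsf1a (−0.22), Atf4 (−0.27), Bax (−0.23), Cdkn1c (−0.15) and Casp1 (0.084). In ethanol-fed rats it turned at Bcl2l1 (−0.063) and at Daxx, Tapbp and Zbtb22 (−0.21), and the 6h change in carbohydrate-fed rats at Cflar (−0.13), Cfap119 and Rnf40 (−0.054) and Dazl (−0.15). With the region mean the 1h change turned at Tdo2 (−0.028) and the 6h change in carbohydrate-fed rats at Egr3 (−0.076), Col1a1 (−0.018), Reln (−0.069), Dcn (−0.06), Tie1 (−0.073) and Nfkb2 (−0.011). The diet difference turned at Krt19 (0.014) and 6h against 1h at Nfkbia (−0.059). Of the 139 named values past the threshold over all arrays, 9 kept their call with array run, 61 with the region mean, 131 with scaling and 135 with quantile normalization. With the replicate block 138 did, and of 903 with 1 array left out 608 did. Signal over background, as the correlation between neighbouring probes, ran from 0.254 to 0.595 between arrays and limits the small differences. The alternatives for kappaB motifs were not run, since no genome was used.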

Other observations

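The values on peak position, slides and components were chosen only after the data were seen, and no test was run on them; the shares of bound genes by list belong to the peak comparison fixed beforehand, and their differences were not tested.

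By the authors' peaks, binding was spread over other gene groups as well. Of 36 cytokine and JAK-STAT genes 41.7% were bound at 1h in carbohydrate-fed and 66.7% in ethanol-fed rats, and 30.6% and 25.0% at 6h, beside 28.9%, 41.6%, 39.6% and 30.2% of all genes in the peak lists. Of 21 liver transcription factors 71.4% and 81.0% were bound at 1h and 14.3% and 28.6% at 0h, and of 30 glucose and amino acid metabolism genes 66.7% and 80.0% at 1h and 26.7% and 20.0% at 6h. Lipid metabolism genes, 41 of them, were bound at 41.5% and 68.3% at 1h, and growth factor signalling genes, 38 of them, at 42.1% and 52.6%. Apoptosis genes were bound at 35.5% and 64.5% of 31 at 1h, and at 25.8% and 3.23% at 6h. None of 11 Kupffer cell and macrophage markers was bound at 0h in carbohydrate-fed rats, 45.5% were at 1h and 54.5% at 6h, and in ethanol-fed rats 27.3%, 36.4% and 27.3%. Of 12 stellate cell markers 0%, 16.7% and 25.0% were bound at 0h, 1h and 6h in carbohydrate-fed and 0%, 25.0% and 41.7% in ethanol-fed rats, and of 15 lymphocyte and neutrophil markers 13.3%, 26.7% and 46.7%, and 33.3%, 20.0% and 33.3%.

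The most frequent patterns over time were binding at 6h alone in both diets (1270 genes), at 1h in ethanol-fed rats and at no time in carbohydrate-fed rats (1209) and at 1h alone in both diets (1025), and 163 genes were bound at every time in both diets. Within 500 bp of a transcription start lay 16.4 ± 5.42% of the peaks at 0h, 21.3 ± 1.16% at 1h and 22.7 ± 2.28% at 6h in carbohydrate-fed rats (SD, n = 3, 3 and 4) and 16.1 ± 3.42%, 18.2 ± 6.71% and 23.1 ± 1.49% in ethanol-fed rats. From 500 to 2000 bp upstream lay 36.3 ± 2.56% at 0h and 25.4 ± 1.84% at 6h in carbohydrate-fed and 33.3 ± 3.43% and 25.1 ± 0.502% in ethanol-fed rats. Over all 20 arrays the mean signal of apoptosis promoters lay above that of other promoters on 5 arrays (difference −0.02 log2, exact sign test, two-sided, p = 0.0414, BH-adjusted 0.365 over 19 lists), and that of stellate cell markers likewise on 5 (−0.07, with the same p values). Both mix times. Apoptosis promoters lay above on 1 of 6, 4 of 6 and 0 of 8 arrays at 0h, 1h and 6h, and stellate cell markers on 0 of 6, 0 of 6 and 5 of 8.

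The first principal component of promoter signal held 34.4% of the variance, of which time explained 73.9%, array run 55.9%, slide 82.1% and diet 0.595%. These shares come from separate fits, and slide, run and time overlap. They also grow with the number of levels (11 slides, 4 runs), so they do not rank the factors. On 3 slides that held both diets at 1h, the ethanol minus carbohydrate differences correlated across promoters, which are not independent, at r = 0.347 between the slides of replicates 2 and 3 of the third run, and at 0.0329 and 0.148 between the slide of the second run and these. Arrays on 1 slide had a consensus correlation of 0.191, and arrays of 1 animal number 0.0722.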
